A study of Mus musculus with 4 samples.

How the data were processed

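RNA of whole mouse kidney was labelled as biotinylated cRNA from 6 µg of total RNA and hybridised to Affymetrix arrays, per the labels' protocols. The series holds 4 arrays, 1 for each of 4 groups, which are Saline+Water, Saline+Captopril, GN+Water and GN+Captopril. The labels describe groups of 6 mice and do not say whether an array carried RNA of 1 mouse or of several.

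The deposited values are log2 probe set values, 1 for each of 22690 probe sets per array, as judged from their range. The submitters' processing notes name the programs GCOS and RMA, without a version or a role for either. The background correction, the normalisation step and the genome build are not given in the sources used here. The medians of the 4 arrays lay between 6.93 and 6.99, and the distributions were close but not identical. The values were used as deposited, and no detection calls were used here.

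Probe sets were named through the platform annotation, with symbols updated through the Entrez ID by a mouse gene table of assembly GRCm38.p6. Of the 22690 probe sets, 20393 had 1 symbol, 691 had several and 1606 had none, and 20364 were named through the Entrez ID. Only probe sets with 1 symbol were named. Coordinates were not used here, because the build of the array's probe definitions is not stated. A gene was represented by its probe set with the highest mean over the 4 arrays, and was kept when that mean reached the 40th percentile of all probe sets, 6.27 on the log2 scale. This left 8207 of 12394 genes, of which 3990 had more than 1 probe set.

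The design crosses 2 factors with 1 array per cell, which leaves 0 residual degrees of freedom unless GN and captopril are assumed to add up. A fit on that assumption would leave 1, and was not run here, since the comparisons ask whether the GN difference depends on captopril. No p-value, standard error or standard deviation between animals is given, and the number of arrays limits the precision of every value. Each of 4 comparisons is a log2 difference between 2 arrays, and genes at least 2-fold apart were counted. For 32 gene lists on kidney cell types, immune cells, injury and metabolism, the median difference of the members past the filter was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile among them describes these arrays only. Members at least 1.5-fold higher or lower were also counted. Across genes, Pearson and Spearman correlations compared the GN difference on water with that on captopril, and the captopril difference in saline mice with that in GN mice; in each case the pairs share no array. Genes are not independent replicates, so these correlations carry no p-value. The size of the GN difference on captopril relative to water was the median, over genes whose mean GN difference was at least 1 on the log2 scale, of the captopril pair minus the water pair in the direction of the mean.

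The comparisons, gene lists and alternatives, and the rule for named genes, were fixed before the data were examined. Named genes were the 12 highest and 12 lowest in the comparison of GN+Water with Saline+Water and in that of GN+Captopril with GN+Water, and the 6 highest and 6 lowest in the other two. To these were added up to 4 members of each list with the largest absolute difference, the 12 with the largest mean GN difference in each direction with the same sign in both pairs, and Ren1, Agt, Ace and Agtr1a. Ren1 and Agtr1a had no probe set with a single symbol in the annotation used here. Nor had the Y-linked Ddx3y, named by a check of sex markers that was set after Eif2s3y had been seen. Other genes named below were chosen after their values were seen and are marked as such. A level was called near background when it lay at or under the 90th percentile of 27 negative-control probe sets of the same array. A fold against such a level is given as a lower bound taken from that percentile. This definition, the tolerances used to compare alternatives and the choice of which list medians count as main results (at least 5 members, a median of at least 0.5 in size, outside the random range) were set after an exploratory look at the data. A level a little over the background limit, which was 4.36 to 4.81, may still be background, and its fold is given as measured. Examples are Slco1a1 at 4.96 on the array labelled GN+Water and Igk at 5.05 on Saline+Water.

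Alternatives were another expression filter, median centring, quantile normalisation, cyclic loess, the mean of all probe sets of a gene, leaving out probe sets shared between transcripts or genes, other fold thresholds, a threshold of 4 local spreads, the mean over list members and list members in no other list. Further alternatives, chosen after seeing the data, put the GN+Captopril array in place of the array labelled GN+Water, or Saline+Captopril in place of Saline+Water, or, for the size comparison, took the genes from the captopril pair and Saline+Captopril as the baseline of both GN arrays. On simulated arrays for the comparison of GN with saline on water, with 8208 genes tested and noise of SD 0.12, 93.5% of 200 genes shifted by 1.5 log2 units were called at 2-fold. That noise was smaller than real differences between arrays, whose SD across genes was 0.24 to 0.78, so false calls were not tested. All 13 missed genes had dropped below the expression filter. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1, and plots used matplotlib 3.10.9.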

Results

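Gene expression was measured in whole kidneys of C57BL/6 mice, labelled male and 17 weeks old, in a model of chronic glomerulonephritis (GN), an inflammation of the kidney's filtering units. GN was induced by intraperitoneal apoferritin, a foreign protein, at 10 mg on 5 days a week, together with 100 µg of lipopolysaccharide 3 times a week, over 6 weeks. Control mice were injected with 0.15 M NaCl. Mice drank water or received 100 mg/kg/day of captopril, an inhibitor of angiotensin converting enzyme, and kidneys were taken after 9 weeks. The study asked whether this drug lessens interstitial kidney injury in the model. There was 1 array per group, so no difference below has a replicate check or an error.

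The array labelled GN+Water carried sex-linked transcripts that go against its male label. Xist, the RNA of the inactive X chromosome, was at 8.97 (log2) on this array and between 5.02 and 5.21 on the other 3 arrays. Its 3 probe sets exceeded the highest other array by 5.49, 3.76 and 0.59. The Y-linked gene Eif2s3y was at 3.43, near background, against 8.02 to 8.29 on the others. Uty, also Y-linked, was at 4.27 on it and between 6.30 and 6.34 elsewhere, and Kdm5d was at 3.52 against 4.63 to 5.69. Both lay near background on this array, and Kdm5d did so on Saline+Water as well. The array is therefore called "the array labelled GN+Water" throughout, and every direction drawn from it carries this limit. Xist, Kdm5d and Uty were added after Eif2s3y had been seen among the named genes.

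The Saline+Water array stood apart from the other 3 in its controls. The median of 18 spike-in probe sets, which no mouse transcript feeds, was 10.8 on Saline+Water and between 7.46 and 7.89 on the others. By transcript, Saline+Water exceeded the highest other array by 1.73 for bioB, 2.88 for bioC, 1.04 for bioD and 0.70 for cre. Its negative controls had a median of 4.17, against 3.63 to 3.70, and its 18S ribosomal RNA controls a median of 6.32, against 7.74 to 8.30. Over all probe sets its Pearson correlation with the other arrays was 0.945 to 0.966, while the other 3 correlated with each other at 0.982 to 0.994. The 3′ minus 5′ difference of the beta-actin control probe sets, a measure of RNA integrity, was between 0.51 and 0.74 on all 4 arrays.

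**Figure D1:**
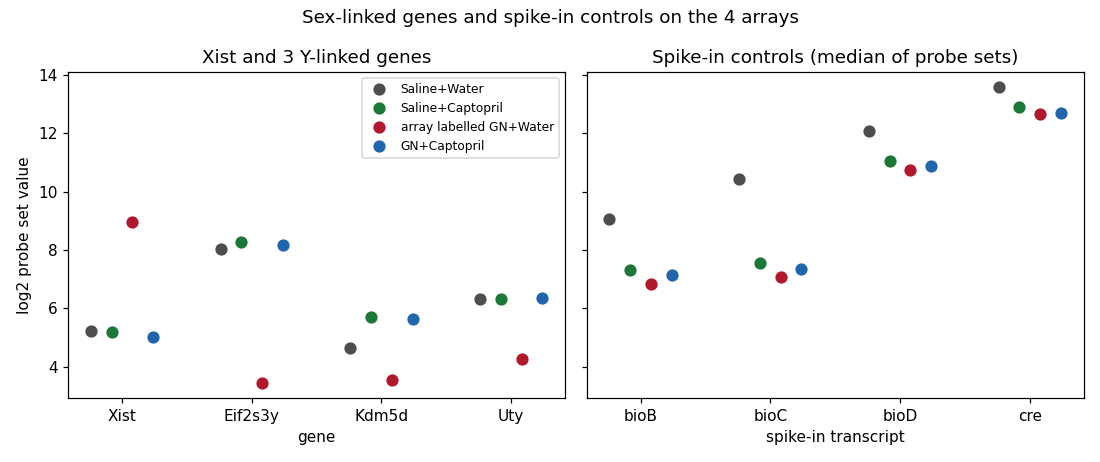
Log2 values of Xist and 3 Y-linked genes (left) and medians of the spike-in control probe sets bioB, bioC, bioD and cre (right), 1 point per array. Xist is at 8.97 on the array labelled GN+Water and at 5.21 or less on the others, and bioC is at 10.4 on Saline+Water and at 7.55 or less on the others. The smallest spike-in difference is that of cre, at 13.6 on Saline+Water and 12.9 or less on the others.

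The first comparison asks how kidneys with GN differed from saline kidneys in mice drinking water. Antibody, macrophage and complement transcripts were higher on the array labelled GN+Water than on Saline+Water, and a group of androgen-responsive tubular transcripts was lower; markers of adipose tissue were higher too. Of 8207 genes, 849 were at least 2-fold higher and 363 at least 2-fold lower. Jchain, which joins antibody units into polymers, was at least 201-fold higher than on Saline+Water, where it lay near background, and 86.6-fold higher than on Saline+Captopril. Ighm, the heavy chain of IgM, was 105-fold higher and the acute phase gene Saa3 was 26.3-fold higher. This comparison uses both the array with discordant sex markers and the array with discordant spike-ins. With Saline+Captopril in place of Saline+Water, a choice made after seeing the data, 205 genes were higher and 92 lower, and with a threshold of 4 local spreads 94 genes passed in all. Of 130 genes examined singly in this comparison, 10 changed direction with that baseline. The fold moved by over 1.5 times for 67 of the 130, for 62 of them to a smaller fold, and some genes are in both counts. For genes named here that moved this far, the fold relative to Saline+Captopril follows in brackets.

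Immunoglobulin and plasma cell genes had a median difference of 3.78 over 8 measured members, of which 5 were at least 1.5-fold higher and 1 lower. Iglv1 was 130-fold, Ighg3 65.0-fold and Igk 102-fold higher. Probe sets of these genes did not all point the same way: 8 of 11 did for Ighm, 2 of 4 for Ighg3 and 1 of 2 for Iglv1, and sequence shared between antibody genes makes the identity of each uncertain. The list median was 0.76 when all probe sets of a gene were averaged and 6.37 with a filter at the 60th percentile, the lowest and highest of its alternatives. In the macrophage, monocyte and dendritic cell list, 18 of 21 members were at least 1.5-fold higher and 0 lower, with a median of 1.76 against a 95% range of −0.31 to 0.32 for random lists. The lysozyme genes Lyz1 and Lyz2 were 20.8-fold (11.2-fold) and 14.5-fold higher, and Ctss, a protease of antigen-presenting cells, 9.45-fold (4.74-fold). The 3 probe sets of Lyz1 differed by 0.08 to 4.38 log2 units. The one used is of a kind shared between transcripts or genes, so Lyz1 may not be separate from Lyz2. B and T lymphocyte genes had a median of 0.68, with 6 of 9 members at least 1.5-fold higher, among them the leukocyte gene Ptprc at 10.96-fold (3.29-fold), which was at 5.98 on Saline+Water and 7.71 on Saline+Captopril. The lymphocyte median was 0.28 without an expression filter and 1.47 over the 3 members left by a filter at the 60th percentile. With GN+Captopril in place of the array labelled GN+Water it was 0.34, and the macrophage median 1.06.

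Complement genes, part of the innate defence that antibody complexes activate, had a median difference of 1.05, with 9 of 16 members at least 1.5-fold higher and 0 lower. The C1q chain genes C1qb, C1qa and C1qc were 6.63-fold, 4.59-fold and 4.50-fold higher. The complement median was 0.54 with GN+Captopril in place of the array labelled GN+Water, and 0.26 without an expression filter. For MHC class II and antigen presentation the median was 1.002, with 12 of 16 members at least 1.5-fold higher, including Psmb8 at 3.11-fold and H2-Eb1 at 2.79-fold. Interferon response genes had a median of 0.77, with 14 of 22 higher, such as Gbp3 at 9.08-fold and Iigp1 at 3.99-fold. Chemokines, cytokines and adhesion molecules had a median of 0.61, with 12 of 22 higher and 2 lower. Ccl8 was 12.6-fold (8.14-fold) and Cxcl13, which attracts B cells, 6.24-fold higher. Without an expression filter this median was 0.35.

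Injury and matrix genes were higher as well. Tubular injury genes had a median of 0.61, with 16 of 30 members at least 1.5-fold higher and 2 lower. Lcn2, a widely used marker of tubular damage, was 7.30-fold (4.54-fold) higher and Anxa1 3.84-fold (2.48-fold). In the extracellular matrix and fibrosis list the median was 0.72, with 27 of 50 members higher and 2 lower, including Lum at 4.86-fold and Col6a1 at 4.03-fold (2.28-fold). Acute phase genes had a median of 0.64, with 6 of 11 higher and 1 lower, and Cp, the copper-carrying ferroxidase, was 5.43-fold higher. Adipose genes, from a tissue next to the kidney, had a median of 0.77, above the random range of −0.39 to 0.52, with Adipoq at 4.05-fold (1.39-fold) higher. That median was 0.22 with Saline+Captopril in place of Saline+Water, and −0.02 without an expression filter. With GN+Captopril in place of the array labelled GN+Water the injury, matrix and acute phase medians were 0.25, 0.19 and 0.01. The acute phase median was 0.005 without an expression filter and 1.54 with one at the 60th percentile.

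Androgen-responsive kidney genes had a median difference of −1.93, with 11 of 17 members at least 1.5-fold lower and 1 higher. Acsm3 was 77.3-fold lower, the organic anion transporter gene Slco1a1 45.4-fold, Cyp2j13 41.0-fold and Cyp7b1 22.1-fold (35.2-fold). Acsm3 stood at 6.20 on the array labelled GN+Water and between 12.5 and 12.6 on the other 3 arrays, and this is the array on which Xist was high and the Y-linked genes low. Slc7a12, an amino acid transporter gene known to be more abundant in the female mouse kidney, was 39.4-fold (21.9-fold) higher and stood at 12.5 against 7.21 to 8.38. Proximal tubule genes had a median of −0.18, with 9 of 41 lower and 3 higher, led by Slc7a13 at 64.6-fold lower. With GN+Captopril in place of the array labelled GN+Water, the androgen-responsive median was 0.20 and the proximal tubule median 0.12. Malat1 was 11.4-fold (1.84-fold) lower, with a level of 11.4 on Saline+Water and between 7.84 and 8.72 on the others.

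Podocyte and endothelial lists lay within the random range, with medians of 0.24 in each case over 16 and 25 members. The loop of Henle and distal convoluted tubule list (median 0.10) and the collecting duct list (0.11) also did. Ace, the gene of captopril's target, was 2.27-fold (1.40-fold) lower and Agt, the angiotensin precursor gene, 1.08-fold lower, or 1.10-fold higher relative to Saline+Captopril. The renin-angiotensin and kallikrein-kinin list had a median of −0.12 over 11 members, and Mme, a peptidase gene of the same list, was 5.66-fold (1.62-fold) higher, with a level of 7.35 on Saline+Water and between 8.8 and 9.85 on the others.

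**Figure D2:**
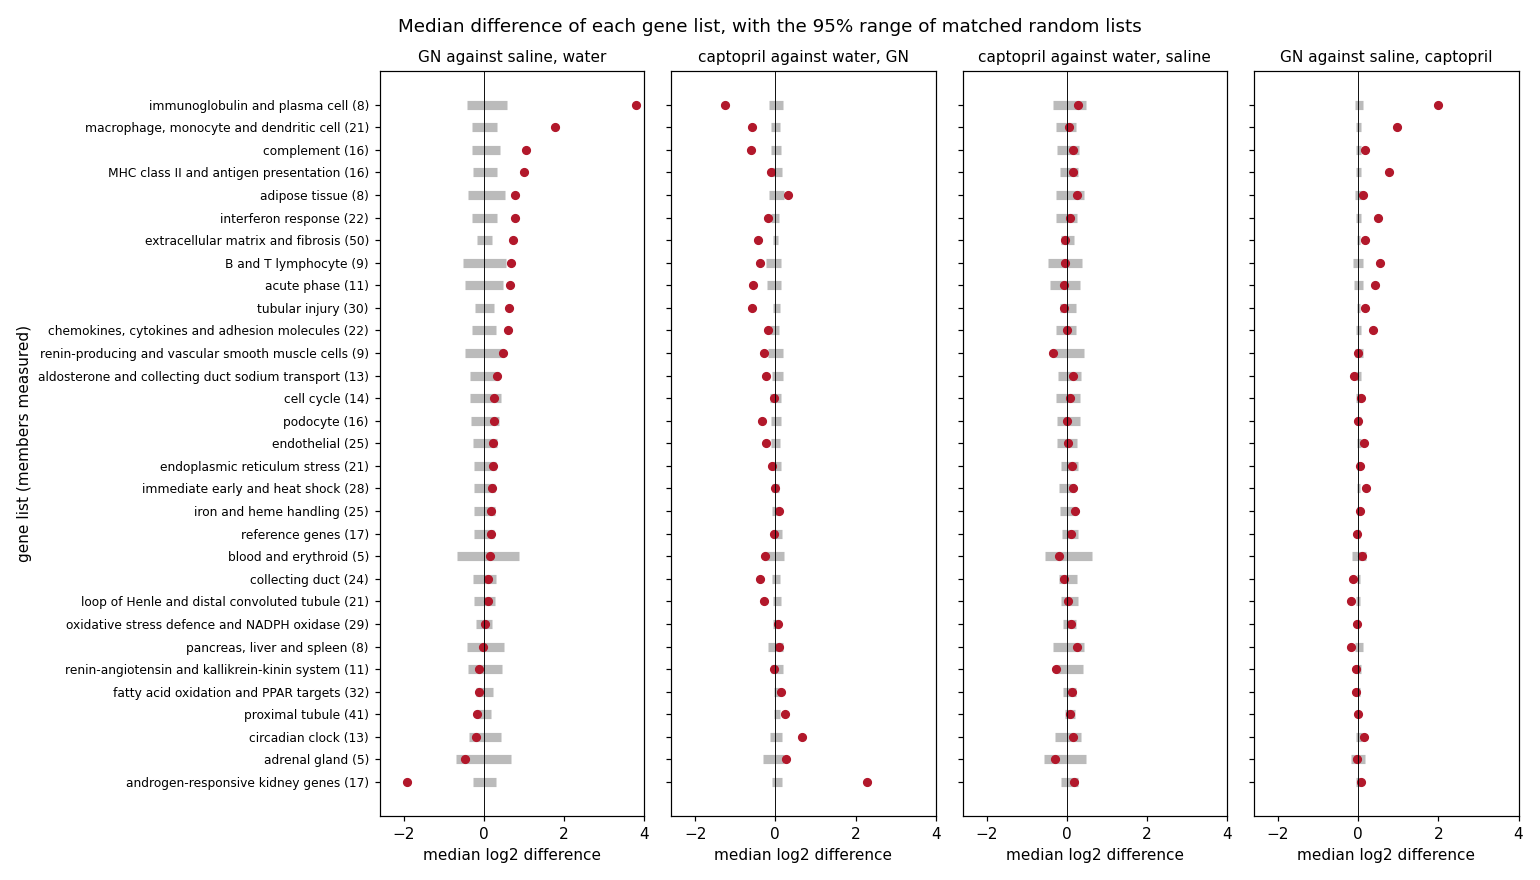
Median log2 difference of each gene list with at least 5 measured members (red points; members in brackets) in the 4 comparisons, with the 95% range of matched random lists in grey. The macrophage list lies at 1.76 in the GN comparison on water, −0.59 for captopril in GN, 0.05 for captopril in saline mice and 0.97 in the GN comparison on captopril.

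The second comparison asks how captopril-treated GN kidneys differed from GN kidneys on water. Androgen-responsive genes were higher on GN+Captopril than on the array labelled GN+Water, and antibody, macrophage, complement, injury and matrix genes were lower. At the 2-fold threshold, 114 genes were higher and 92 lower, while at 1.5-fold 304 were higher and 371 lower. The highest were Slc7a13 at 101-fold, Acsm3 at 83.0-fold, Slco1a1 at 50.5-fold, Cyp2j13 at 46.5-fold and Cyp7b1 at 36.7-fold. The Y-linked Eif2s3y was at least 14.1-fold higher. Lowest were Slc7a12 at 17.6-fold lower and the organic anion transporter family gene Slc22a29 at 8.68-fold. Akr1c18, which inactivates progesterone and is more abundant in female mouse kidney, was 6.28-fold lower. The comparison cannot be made without the array whose sex markers go against its label.

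The androgen-responsive list had a median of 2.29, with 12 of 17 members at least 1.5-fold higher and 1 lower. Proximal tubule genes had a median of 0.23, with 13 of 41 higher and 1 lower, among them Cyp2e1 at 6.91-fold. Sex-linked transcripts differed in the same pair of arrays, with Xist at 8.97 on the array labelled GN+Water and 5.02 on GN+Captopril.

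Immune lists lay below the range of random lists, on arrays that also differ in these sex-linked transcripts. Immunoglobulin and plasma cell genes had a median of −1.25, with 5 of 8 members at least 1.5-fold lower and 1 higher. Igk was 6.98-fold and Jchain 4.02-fold lower. Averaging all probe sets of a gene gave −0.49, and leaving out the expression filter −0.80. Macrophage, monocyte and dendritic cell genes had a median of −0.59, with 11 of 21 lower and 0 higher. Adgre1, the F4/80 macrophage marker, was 2.03-fold lower and Fcgr3, an Fc receptor gene, 1.85-fold. Complement genes had a median of −0.60, with 8 of 16 lower and 1 higher, and C1qa was 2.06-fold lower. For MHC class II and antigen presentation the median was −0.12, with 1 of 16 members at least 1.5-fold lower, and for interferon response genes −0.19, with 4 of 22 lower. Gbp3 was 4.65-fold lower. In the chemokine, cytokine and adhesion list the median was −0.19, with 5 of 22 lower, including Cxcl13 at 3.07-fold. The B and T lymphocyte median was −0.39, with 2 of 9 lower.

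Tubular injury genes had a median of −0.58, with 15 of 30 members at least 1.5-fold lower and 0 higher. Lcn2 was 3.42-fold and Fgb, a fibrinogen chain gene, 2.55-fold lower. In the extracellular matrix and fibrosis list the median was −0.43, with 16 of 50 lower and 1 higher. Lum was 2.63-fold and Col3a1 1.91-fold lower, and Col1a1 was 2.01-fold lower in 1 of 2 probe sets only. Acute phase genes had a median of −0.55, with 5 of 11 lower, and Saa3 was 3.61-fold lower; the median was −0.25 without an expression filter and −0.98 with one at the 60th percentile. Podocyte (−0.32), endothelial (−0.24), loop of Henle and distal convoluted tubule (−0.28) and collecting duct (−0.39) medians also lay below the random range, with 3 of 16, 4 of 25, 5 of 21 and 6 of 24 members at least 1.5-fold lower. Sgk1, an aldosterone-induced kinase gene, was 3.89-fold lower, and the aldosterone and collecting duct sodium transport list had a median of −0.23. Of the neighbouring tissues, adipose genes (median 0.30, 3 of 8 members at least 1.5-fold higher and 1 lower) and adrenal genes (0.25, 1 of 5 higher) lay above the random range; without an expression filter the adipose median was 0.10 and the adrenal median 0.16. Ace was 1.43-fold higher and Agt 1.26-fold lower.

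**Figure D3:**
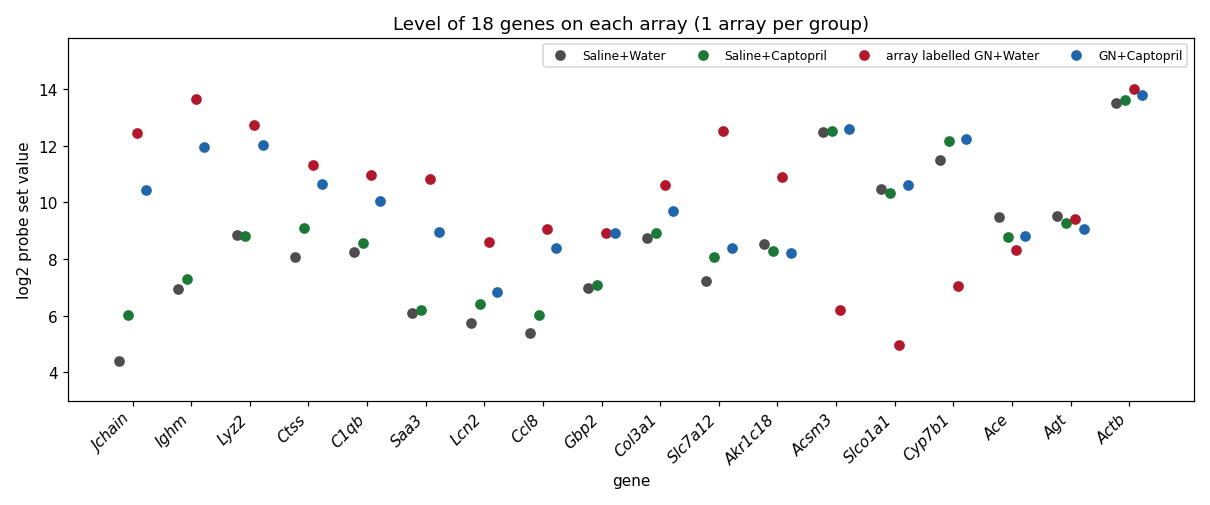
Log2 level of 18 genes on each array, 1 point per array. Acsm3 is at 6.20 on the array labelled GN+Water and at 12.5 or more on the others, while Lyz2 is at 12.7 and 12.01 on the GN arrays and at 8.86 and 8.81 on the saline arrays.

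The third comparison asks how saline-injected mice on captopril differed from those on water. The heat shock genes Hspa1b and Hspa1a were higher on Saline+Captopril than on Saline+Water, and no immune or injury list left the random range. In all, 528 genes were at least 2-fold higher and 171 lower. Hspa1b, an inducible heat shock protein gene, was 8.77-fold higher, Hspa1a 4.92-fold, Tex10 6.69-fold, Ppp3cb 6.62-fold and Pbrm1 6.55-fold. Tex10 was at 5.14 on Saline+Water and 7.88 to 8.17 on the other arrays, Ppp3cb at 6.49 against 9.22 to 9.35 and Pbrm1 at 6.53 against 9.24 to 9.34. Hspa1b was at 6.93 against 8.60 to 10.1. The other arrays include the array labelled GN+Water, whose group received no captopril. Bex1 was at least 7.93-fold higher, with a level near background on Saline+Water. Pvalb, a calcium-binding protein gene of the distal convoluted tubule, was 9.52-fold lower, Malat1 6.21-fold and the basement membrane collagen gene Col4a3 3.81-fold. Pvalb stood at 9.31 on Saline+Water and between 5.57 and 7.44 on the other 3 arrays. This comparison rests on the array with discordant spike-ins and cannot be made without it. When all probe sets of a gene were averaged, 440 genes passed in place of 699. At 4 local spreads 68 passed, 63 higher and 5 lower, and at 1.5-fold 1278 were higher and 835 lower.

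Macrophage (0.05), complement (0.16), immunoglobulin (0.29), tubular injury (−0.08) and matrix (−0.05) medians lay within the random range. The renin-angiotensin and kallikrein-kinin list had a median of −0.26, just below its random range of −0.25 to 0.40, with 3 of 11 members at least 1.5-fold lower and 3 higher; the mean over its members was 0.04. Ace was 1.62-fold lower, Agt 1.20-fold lower, Mme 3.49-fold higher and Atp6ap2, the prorenin receptor gene, 2.20-fold higher. The array labelled GN+Water, whose group received no captopril, differed from Saline+Water in the same directions. On it Ace was 2.27-fold lower, Agt 1.08-fold lower, Mme 5.66-fold higher and Atp6ap2 2.41-fold higher. On GN+Captopril relative to that array, Ace was 1.43-fold higher, Mme 2.06-fold lower and Atp6ap2 1.15-fold lower, each the other way. Agt was 1.26-fold lower there, the same way. Fatty acid oxidation and PPAR target genes had a median of 0.13 within the random range, with Cyp4a14 at 5.30-fold and Fabp1 at 3.11-fold higher.

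The fourth comparison asks how GN differed from saline in mice on captopril. It uses neither the array with discordant sex markers nor the one with discordant spike-ins, but markers of neighbouring tissues differed in it. Adipose genes had a median of 0.12, above the random range of −0.08 to 0.10, with 2 of 8 members at least 1.5-fold higher, Adipoq at 2.22-fold and Fabp4 at 1.66-fold. Pancreas, liver and spleen genes had a median of −0.19, below the random range of −0.09 to 0.11, with 0 of 8 members 1.5-fold lower, and −0.03 with a filter at the 60th percentile. Antibody, macrophage, interferon and antigen presentation genes were higher on GN+Captopril than on Saline+Captopril. At 2-fold, 59 genes were higher and 2 lower. The highest were Igkv8-30 at 32.9-fold, Ighm at 25.4-fold, Iglv1 at 21.7-fold and Jchain at 21.5-fold. The 2 lower genes were Hspa1b at 2.76-fold and Bcl6, a transcriptional repressor gene of B and T cells, at 2.25-fold. At a threshold of 4 local spreads, 187 genes were higher and 45 lower.

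Macrophage, monocyte and dendritic cell genes had a median of 0.97 against a random range of −0.06 to 0.07, with 16 of 21 members at least 1.5-fold higher and 0 lower. Lyz2 was 9.17-fold, Lyz1 7.06-fold and Cybb, the catalytic subunit gene of the phagocyte NADPH oxidase, 2.84-fold higher. The Lyz1 value rests on the same probe set as on water, with the same limit. Immunoglobulin and plasma cell genes had a median of 1.98, with 4 of 8 higher. Across its alternatives it lay between 0.18, when all probe sets were averaged, and 3.99, with a filter at the 60th percentile. MHC class II and antigen presentation genes had a median of 0.77, with 11 of 16 higher, including Psmb9 at 2.43-fold and Cd74 at 2.16-fold. The interferon response median was 0.48, with 10 of 22 higher, such as Gbp2 at 3.61-fold and Cxcl9 at 2.87-fold. For chemokines, cytokines and adhesion molecules it was 0.37, with 9 of 22 higher, including Ccl8 at 5.15-fold and Ccl5 at 3.05-fold, and 0.19 without an expression filter. B and T lymphocyte genes had a median of 0.54, with 3 of 9 higher; it was 0.10 over 23 members without an expression filter and 0.96 over 3 members with a filter at the 60th percentile.

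Complement genes had a median of 0.18, with 6 of 16 members at least 1.5-fold higher and C1qc at 3.14-fold. The acute phase median was 0.41, with 2 of 11 higher, 1 of them Saa3 at 6.81-fold, and 0.002 without an expression filter. Injury and matrix differences were smaller, with medians of 0.16 in each list, 6 of 30 injury members and 3 of 50 matrix members at least 1.5-fold higher, and 0 lower. Both medians lay above the random ranges, −0.03 to 0.05 for injury and −0.02 to 0.04 for matrix. Those of complement (range −0.05 to 0.07) and acute phase genes (−0.11 to 0.12) did too. Vim was 1.81-fold, Vcam1 1.70-fold and Col3a1 1.71-fold higher. Loop of Henle and distal convoluted tubule (−0.17) and collecting duct (−0.13) medians lay below the random range, with 1 of 21 and 0 of 24 members at least 1.5-fold lower. The androgen-responsive median was 0.06, with 0 of 17 members 1.5-fold apart, and the podocyte median was −0.01. The endothelial median was 0.14, above the random range of −0.04 to 0.07, with 0 of 25 members 1.5-fold apart. Ace was 1.02-fold higher, with its probe sets pointing both ways, and Agt 1.14-fold lower.

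Antibody genes, lysozyme genes and Saa3 had the highest mean GN difference over the 2 pairs of arrays, which share no array. Among the 12 highest were Jchain (at least 7.65 on water and 4.43 on captopril), Igkv8-30 (6.48 and 5.04), Iglv1 (7.02 and 4.44), Ighm (6.71 and 4.67), Saa3 (4.72 and 2.77) and Lyz2 (3.86 and 3.20). Among the 12 lowest with the same sign were Pzp (−4.63 and −0.08) and Malat1 (−3.51 and −0.09), whose captopril differences were near 0. Eif2s3y, also among them, was lower by at least 3.65 on water and differed by −0.10 on captopril. Bcl6 differed alike in both (−1.23 and −1.17). Across 8207 genes the GN differences correlated at r = 0.31 (Spearman rho 0.086). Both pairs placed 49 genes at least 2-fold higher, where independent lists would share 6.10. They placed 1 gene lower in both, against 0.088, and 3 in opposite directions, against 2.82.

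**Figure D4:**
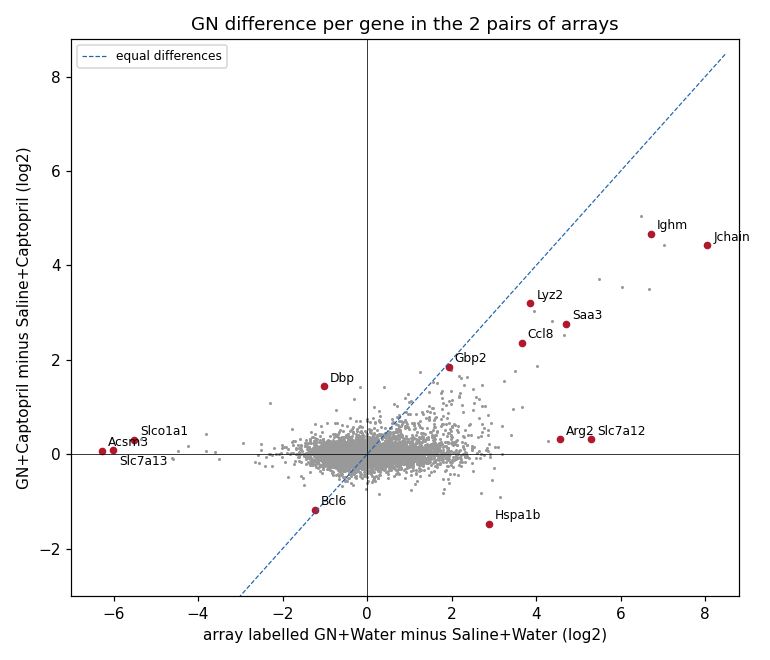
GN minus saline log2 difference of each of 8207 genes on water (x axis, array labelled GN+Water minus Saline+Water) and on captopril (y axis). Ighm lies at 6.71 and 4.67, while Acsm3 lies at −6.27 and 0.07.

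Captopril differences in saline and GN mice correlated across genes at r = −0.096 (rho −0.16), while genes at least 2-fold apart in both pairs more often shared a direction than independent lists would. There were 15 genes at least 2-fold higher in both, against 7.33 for independent lists, 6 lower in both, against 1.92, and 11 in opposite directions, against 8.29. Each of these pairs contains 1 of the doubtful arrays.

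The size of the GN difference was smaller on captopril than on water. Over 259 genes with a mean GN difference of at least 1, the captopril pair was below the water pair by a median difference of −1.88 (interquartile range across genes −2.35 to −1.22), with medians of 2.20 on water and 0.32 on captopril. The difference was smaller on captopril for 254 of the 259 genes. Both doubtful arrays are in the water pair, and choosing genes on the mean favours the pair with larger differences. Over all genes the SD of the difference was 0.78 on water and 0.24 on captopril. Relative to that spread the order turned, with 94 genes passing 4 local spreads on water and 232 on captopril. Among the 59 genes at least 2-fold higher in GN+Captopril than in Saline+Captopril, a choice made after seeing the data that also leaves out Saline+Water, 48 were lower on GN+Captopril than on the array labelled GN+Water, with a median of −0.67. Against Saline+Captopril, these 59 genes had medians of 1.38 on GN+Captopril and 2.01 on the array labelled GN+Water.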

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

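The tests of a hybridisation batch, of the Saline+Water baseline, of saline arrays with the same sex markers, of a pool with males and of direction among genes of like intensity were chosen only after the results they bear on had been seen. The sex marker test was set before Xist, Kdm5d and Uty were looked at, but after Eif2s3y and the androgen-responsive genes had been seen. None of the differences between groups below was tested, since each group has 1 array.

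Xist, which the expression filter leaves out of the comparisons, was 3.76 log2 units higher on the array labelled GN+Water than on any other array. The androgen-responsive list had a median GN difference of −1.93 on water and 0.06 on captopril, and the second minus the first was 1.99. The value on captopril lay just above its random range, with 0 of 17 members 1.5-fold apart. A mislabelled array is a candidate explanation: RNA of female mice needs high Xist (3.76) and low Y-linked genes, and Uty was lower by at least 1.93 than on the other arrays, while the measured median of Kdm5d and Uty (−1.57) includes levels near background, for Kdm5d on Saline+Water too. Loss of androgen action in male mice with GN is argued against as the whole cause, since it forbids that Xist level and Eif2s3y at least 12.5-fold below the other arrays. A pool of 6 mice in equal shares with at least 1 male is argued against by the same 12.5-fold, since it would leave Eif2s3y at most 6-fold lower; a smaller male share and any further effect of GN on these genes stay open.

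The median of the spike-in controls, which belong to no comparison, was 2.96 log2 units higher on Saline+Water than on the highest other array. By transcript, Saline+Water was higher by 1.73 for bioB, 2.88 for bioC, 1.04 for bioD and 0.70 for cre, each less than 2.96. An effect of captopril as the whole reason for this array standing apart is argued against, provided that captopril acts alike in saline and GN mice. The 699 genes at least 2-fold apart in the saline pair had a median of −0.066 in the GN pair, taken in the direction of the saline pair. Of them 39.8% shared that direction, although the GN pair holds the array labelled GN+Water. That array, whose group received no captopril, correlated at 0.982 with Saline+Captopril and at 0.945 with Saline+Water. Intensity-dependent scaling is argued against only as a shift left in the deposited values. In 10 groups of genes by intensity, the median difference of the saline pair was −0.044 to 0.068, far from 2-fold. With medians so near 0, genes 2-fold apart fall on both sides, so the test of direction decides nothing. In each group at least 15.7% of them went against the rest. Cyclic loess, after which 689 genes passed, shifted this pair by at most 0.15 and decides nothing either. A separate hybridisation batch stays a candidate, since the spike-in median was higher by 2.96, though cre was higher by 0.70 only. Whether labelling differed was not tested, and the labels used here give no batch. Part of the 699 may still be captopril, and batch and drug cannot be separated with 1 array.

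Immune and matrix lists were further from saline on the array labelled GN+Water than on GN+Captopril. The Saline+Water array as the baseline is argued against as the whole cause, for the macrophage, complement and matrix lists only. Together they were higher by a median of 0.51 on the array labelled GN+Water than on GN+Captopril, in 90.8% of 87 genes. No saline array is involved, and the values are those of the second comparison. They cannot show that the baseline adds nothing. With Saline+Captopril in place of Saline+Water, the median on the array labelled GN+Water was 0.59 in place of 0.72 for matrix. It was 1.64 in place of 1.76 for macrophage genes, and 1.07 in place of 1.05 for complement. Among other immune lists, GN+Captopril differed from the array labelled GN+Water by −1.25 for immunoglobulin and −0.39 for lymphocyte genes. For MHC class II, interferon and chemokine lists the medians were smaller, at −0.12, −0.19 and −0.19, so the baseline stays open there. The different sex markers and an effect of captopril cannot be told apart, because 0 saline arrays carry the same sex markers. A lessening of the immune and matrix response by captopril, which the design names, therefore stays a hypothesis that these arrays leave untested.

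Hspa1b had GN differences of at least 2-fold in opposite directions, and that on captopril minus that on water was −4.35. Relative to Saline+Captopril, Hspa1b on the array labelled GN+Water differed by −0.25, so its opposite directions rest on the Saline+Water array. For Dbp, a circadian output gene, the same value was 2.47, and for the carboxylesterase gene Ces1g it was 3.39. Captopril differences of at least 2-fold in opposite directions in saline and GN mice were seen for 11 genes, where independent lists would give 8.29. Each of these pairs contains a doubtful array. These were Arg2, Cldn1, Cyp4a14, Elovl2, Fabp1, Fabp5, Gsta2, Hspa1b, Jchain, Mme and Nap1l5, all higher on captopril in saline mice and lower in GN mice. Jchain in the saline pair is measured against a level near background. Those of the 11 genes outside the naming rule were chosen after their values were seen.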

How the results depend on the processing

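The swaps of 1 array for another and the size comparison on genes of the captopril pair with Saline+Captopril as the baseline were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group has 1 array. No alternative could leave out a doubtful array from the captopril comparisons, and the arrays' negative controls, at medians of 3.63 to 4.17, limit what can be read for dim genes. Both correlations of differences kept their sign and moved by less than 0.1 under the 7 settings tried. Of 2510 recalculated single-gene differences 2447 stayed within 1 SD of their comparison, 61 moved further and 2 changed sign. Of the recalculated list medians, 182 of main results and 930 of others stayed within a tolerance set by the width of their random range, 47 and 44 moved further, and 2 and 3 changed sign. Except where construction is named, the cause was not tested.

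Stricter or looser thresholds changed the counts by construction. The count for the array labelled GN+Water against Saline+Water was 2861 at 1.5-fold, 388 at 3-fold, 94 at 4 local spreads and 800 with a filter at the 60th percentile. GN+Captopril against the array labelled GN+Water gave 675 at 1.5-fold and 81 at 3-fold. Saline+Captopril against Saline+Water gave 2113 at 1.5-fold, 148 at 3-fold, 68 at 4 local spreads, 464 with the stricter filter and 440 when probe sets were averaged. GN+Captopril against Saline+Captopril gave 169 at 1.5-fold, 21 at 3-fold, 232 at 4 local spreads and 38 with the stricter filter. With Saline+Captopril in place of Saline+Water, the first count was 297. The size of the GN difference was −0.67 when the genes were chosen from the captopril pair and Saline+Captopril was the baseline of both GN arrays, 2 choices changed together.

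With GN+Captopril in place of the array labelled GN+Water, medians against Saline+Water were 0.54 for complement, 2.21 for immunoglobulin, 1.06 for macrophage, 0.01 for acute phase (0.013), 0.25 for tubular injury and 0.19 for matrix. The androgen-responsive median was 0.20 and the proximal tubule median 0.12, both with the opposite sign. With Saline+Captopril in place of Saline+Water, the androgen-responsive median was −2.29 and the adipose median 0.22.

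Without an expression filter, which adds dim members, the GN medians on water were 0.26 for complement, 1.31 for immunoglobulin, 1.21 for macrophage, 0.005 for acute phase (0.00512) and −0.023 for adipose genes, the last with the opposite sign. For captopril in GN they were −0.42 for complement, −0.80 for immunoglobulin, −0.25 for acute phase and 0.30 for clock genes, and for GN on captopril 0.40 for immunoglobulin, 0.10 for lymphocytes and 0.79 for macrophages. With a filter at the 60th percentile, which removes members, GN medians on water were 6.37 for immunoglobulin, 1.47 for lymphocytes, 2.22 for macrophages, 1.41 for MHC class II and 1.54 for acute phase. For captopril in GN they were −1.85 for immunoglobulin and −0.98 for acute phase, and for GN on captopril 3.99 for immunoglobulin, 0.96 for lymphocytes, 1.09 for macrophages and 0.86 for MHC class II.

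Averaging all probe sets of a gene gave immunoglobulin medians of 0.76 for GN on water, −0.49 for captopril in GN and 0.18 for GN on captopril, and a macrophage median of 1.05 for GN on captopril. Without shared probe sets the same 4 medians were 1.54, −0.81, 0.41 and 0.89. Without shared probe sets, the captopril differences in saline mice of Aco1 (−0.20) and H2-D1 (−0.53) had the opposite sign. Immunoglobulin members in no other list gave 6.02 for GN on water, −1.69 for captopril in GN and 3.54 for GN on captopril. For aldosterone genes in no other list, GN on captopril gave 0.01 (0.0138), with the opposite sign.

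The mean over members gave, for captopril in GN, −0.43 for complement, −1.01 for immunoglobulin, −0.80 for acute phase and 2.46 for androgen-responsive genes. For GN on captopril it gave 2.22 for immunoglobulin and 1.04 for macrophages. The mean of the renin-angiotensin and kallikrein-kinin list for captopril in saline mice was 0.040, with the opposite sign to its median.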

Other observations

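Clock genes differed between the GN arrays. The circadian clock list had a median of 0.66 on GN+Captopril relative to the array labelled GN+Water, above the random range of −0.12 to 0.16, with 7 of 13 members at least 1.5-fold higher and 1 lower; without an expression filter the median was 0.30. Dbp was 11.2-fold and Tef 2.59-fold higher, while Arntl, the partner of Clock, was 2.54-fold lower. On GN+Captopril relative to Saline+Captopril, Dbp was 2.72-fold higher and Arntl 1.78-fold lower. The labels used here give no hour of tissue collection. Hspa1b was at 6.93 on Saline+Water and between 8.60 and 10.1 on the other 3 arrays, and Hspa1a at 6.08 against 7.64 to 8.37, while Hspb1 was at 10.2 on Saline+Water and 9.64 on Saline+Captopril. The immediate early and heat shock list lay within its random range for captopril in saline mice (median 0.16, range −0.21 to 0.21), with 6 of 28 members at least 1.5-fold higher and 3 lower. In GN relative to saline on captopril its median was 0.20, above the random range of −0.04 to 0.06, with 4 of 28 members higher and 2 lower.

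In the GN comparison on water, iron and heme handling genes had a median of 0.18, within the random range, with 8 of 25 members at least 1.5-fold higher and 4 lower. The iron exporter gene Slc40a1 was 2.97-fold and Heph, a ferroxidase gene, 3.71-fold higher, or 1.76-fold and 1.72-fold relative to Saline+Captopril. Oxidative stress defence and NADPH oxidase genes had a median of 0.02, with Gsta4 at 4.03-fold and Cybb at 3.13-fold higher. Fatty acid oxidation and PPAR targets had a median of −0.13, endoplasmic reticulum stress genes 0.22 and cell cycle genes 0.26, all within the random range. For the aldosterone list the median was 0.33, and for renin-producing and vascular smooth muscle cells 0.48, also within it, with Sgk1 at 3.86-fold and Rgs5 at 2.71-fold higher, or 2.55-fold and 1.43-fold relative to Saline+Captopril.

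Markers of neighbouring tissues were examined in the same comparison. The adipose list is given in the report. Adrenal genes had a median of −0.48, blood and erythroid genes 0.16 and pancreas, liver and spleen genes −0.03, all within the random range. For captopril in saline mice the adipose list and these 3 lay within the random range, and the report gives those outside it in the other comparisons. Of the neutrophil list only Mmp9 passed the filter, at 1.13-fold lower in GN on water, or 1.17-fold higher relative to Saline+Captopril. Relative to Saline+Water, the reference genes had a median of 0.16, with Actb 1.40-fold higher and 1 of 17 members at least 1.5-fold higher.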
